A study of Mus musculus with 2 samples.

How the data were processed

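Total RNA was measured in 2 libraries of the left cerebral cortex of male B6CASTF1/J mice, the F1 hybrid of C57BL/6 and CAST, at an age of 14 days. Per the labels, each library was made from 300 ng of RNA, and ERCC spike-ins, synthetic RNAs added in known amounts, were of the profile for stranded libraries with ribosomal RNA reduced. The labels number the libraries as biological replicates 1 and 2 and name a separate biosample for each, but they also name 1 donor entry for both and speak of 3 males without saying whether tissue was pooled. The labels therefore do not say that the libraries came from separate animals, and the spread between them may be technical. Both libraries form 1 group, so no comparison between conditions exists and no p-value is given. A two-sided exact sign-flip test of 2 libraries cannot go below p = 0.5.

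Per the file headers and the description files deposited with each sample, a gene table and a transcript table were derived from transcriptome alignments on mm10 with GENCODE M21. The deposited expected counts in these tables are estimated reads per gene or transcript, not normalized. The deposited TPM values are relative to all entries of a file, spike-ins included, and the deposited FPKM values are scaled by effective length and by the assigned reads of the library. The deposited percent of each gene's abundance in each transcript stands beside them. A second transcript table per sample was derived directly from the reads with the same annotation, and its deposited estimated counts and TPM values were summed per gene. The column names are those that RSEM writes (gene table and first transcript table) and those that kallisto writes (second transcript table); the aligner, the quantifiers, their versions and the use of strand in counting are not given in the sources used here. Genes that overlap, or that lie antisense to each other, may therefore share reads. Reads of near-identical copies were divided by the quantifiers, so values of single copies are uncertain.

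The gene tables also hold 96 spike-in entries, 1 phiX entry and 26248 entries named only by a number, which took 1 and 6 counts in replicates 1 and 2. These entries were left out of gene counts, library sizes and normalization. Gene symbols, biotypes and coordinates were taken from GENCODE M21 on mm10, matched by versioned identifier for all 55536 genes. Of the 427 genes in the fixed lists, 1 had no match (Oip5os1), and where a symbol had 2 identifiers, as for Rmrp and Dlx6os1, the lowest was used. The second table had no entry for 86 genes.

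Depth was 28377847 expected counts in replicate 1 and 30982776 in replicate 2. A count of 0 allows up to 3 counts, or 0.106 and 0.097 CPM. Shares of counts are given with 95% Wilson intervals, and such intervals and floors cover counting error only. Over 17769 genes with at least 10 counts in both libraries, the chi-square statistic per degree of freedom between the libraries was 11.98, so the files do not hold the counts of 1 and the same library; this does not tell technical from biological spread.

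Differences between the libraries were computed on rounded expected counts as log2 CPM, replicate 2 minus replicate 1, with TMM factors and a prior count of 2 in edgeR 4.0.16 under R 4.3.3, for genes with at least 10 counts in at least 1 library. The common biological coefficient of variation came from edgeR with an intercept as the only term. DESeq2 1.42.0 supplied alternative size factors. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For each of 43 fixed gene lists (24 of cell classes or regions, 19 of gene programs), the median difference was placed as a percentile among 10000 random lists of equal size matched on mean expression. A list was said to stand apart below percentile 2.5 or above 97.5, which describes these 2 libraries only. Within gene pairs the log2 ratio of TPM + 0.1 was taken in each library, and a direction is given only where both libraries share it and the mean exceeds the SD.

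The steps were tested on simulated counts with the real means and library sizes of 18965 genes. With a coefficient of variation of 0.1 and no changed gene, edgeR estimated 0.0996; with 200 genes changed it estimated 0.134, so genes that differ between libraries raise this estimate. All of 100 genes changed 4-fold were found past 2-fold (100%), the median estimate for 100 genes changed 2-fold was 1.01 on the log2 scale, and 0 of 12425 unchanged genes with a mean of at least 100 counts passed. In a simulation of 18965 genes for the percentiles, a list of 11 genes shifted by -1 lay at percentile 0, and 8 of 200 unshifted lists (4.0%) stood apart. Genes varied independently in that simulation, so it does not cover lists whose members vary together. Differences were drawn with the same spread for all genes, so the matching on mean expression was not tested. A shift of -1 was far beyond that spread, so its percentile does not show how smaller shifts would be found.

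The lists, pairs, isoform genes and alternatives were fixed before the data were examined. Named in the text are the 15 nuclear protein-coding genes of highest mean TPM, up to 4 members of highest mean TPM of a list and members below TPM 1 in both libraries, both genes of each pair, the 10 largest differences in each direction among genes with a mean of at least 100 expected counts, and 24 isoform genes. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here. The alternatives covered TPM thresholds, normalization, filters, prior and pseudocounts, units, the second quantification and each replicate left out. Signal tracks and alleles of the 2 parental strains were not analysed here.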

Results

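The cerebral cortex of mice aged 14 days was profiled by total RNA sequencing, a profile of 1 tissue at 1 age in males of a C57BL/6 by CAST hybrid. The 2 libraries, replicates 1 and 2 of 1 group, held 28377847 and 30982776 expected counts. At this depth 15028 genes reached a TPM of 1 in both libraries, of which 12944 were protein-coding and 282 were annotated as lincRNA. Across the genes detected in both, log2 TPM values of the 2 libraries had a Pearson correlation of 0.988, a correlation across genes, which are not independent replicates. The common biological coefficient of variation was 0.107. Values below are mean TPM ± SD (n = 2) unless the 2 libraries are given separately.

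The highest nuclear protein-coding genes were those of the cytoskeleton, translation, synapses and calcium signalling. Actb (1382 ± 15), Eef1a1 (1284 ± 15.9) and Nrgn, a postsynaptic calmodulin-binding protein of forebrain neurons (1189 ± 259), led, followed by Snurf (1073 ± 53.0), Gapdh (1047 ± 1.99), the vesicle protein Syp (1042 ± 36.9), Calm2 (1041 ± 52.3) and Hspa8 (1040 ± 45.6). Cpe (1022 ± 10.1), Tuba1a (1003 ± 34.7), the astrocytic glutamate transporter Slc1a2 (975 ± 37.1), Calm3 (941 ± 44.7) and Cst3 (935 ± 52.9) were also among the first 15. The SD of Nrgn was the largest of the 15, with 1006 TPM in replicate 1 and 1372 in replicate 2. Snurf is annotated as a single transcript of 216 nt (chromosome 7, 59995449 to 60005049, mm10), and its TPM in the second transcript table was 0 in both libraries. The other housekeeping gene among the 4 highest of its list was Ppia (929 ± 66.8), and the 12 housekeeping genes had a median difference between libraries of -0.0011 on the log2 scale.

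Most of the assigned counts belonged to nuclear protein-coding genes, and reads assigned to no entry are not in these shares. Nuclear protein-coding genes took 81.1% of the counts in replicate 1 (95% Wilson interval 81.105 to 81.133) and 81.5% in replicate 2 (81.519 to 81.546). Genes of mitochondrial DNA took 6.91% (6.90 to 6.92) and 7.02% (7.01 to 7.03), mostly in the ribosomal RNAs mt-Rnr2 and mt-Rnr1 (1144540 and 412265 of 1961840 counts in replicate 1). Other nuclear genes took 6.80% (6.79 to 6.81) and 6.44% (6.43 to 6.45), among them Gm26917, annotated as lincRNA, with 776581 and 741115 counts. Gm42418, annotated likewise and next to it on chromosome 17, took 80983 and 79771. Whether the counts of these 2 genes are residual ribosomal RNA was not examined, so they are not evidence of lincRNA expression. Small non-coding RNAs took 4.77% (4.76 to 4.77) and 4.62% (4.61 to 4.62), and spike-ins 0.404% (0.401 to 0.406) and 0.387% (0.385 to 0.389). Because TPM divides by length, the small non-coding RNAs took 37.1% and 36.4% of all TPM. The 7SL RNAs of the signal recognition particle, Rn7s1 and Rn7s2, stood at 137834 ± 1239 TPM each, with equal values since their reads were divided between identical copies. Rn7sk followed at 44467 ± 3325 and Rpph1 at 8138 ± 137, whereas Rny3 was listed at 0 in both libraries. Of mitochondrially encoded messages, mt-Co1 (5499 ± 243), mt-Cytb (2977 ± 140), mt-Nd1 (2617 ± 52.1) and mt-Atp6 (2464 ± 15) were highest. Nuclear copies of mitochondrial sequence share reads with them. The unprocessed pseudogene Gm28661 stood at 6382 ± 324, above mt-Co1. By the second transcript table, mt-Atp6 (7417 and 6585 TPM in replicates 1 and 2) exceeded mt-Cytb (4646 and 4809), so this order depends on the quantification. In the second transcript table small non-coding RNAs took 0.00411% and 0.00357% of counts, and the median ratio of its TPM to that of the gene table over 12882 protein-coding genes was 1.56 in replicate 1 and 1.54 in replicate 2.

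Pan-neuronal genes had the highest median of the cell class lists. The 12 genes had a median of 365 ± 9.43 TPM, against 53.0 ± 4.27 for astrocyte, 44.3 ± 8.08 for excitatory and 38.5 ± 9.31 for inhibitory neuron genes, with Snap25 (721 ± 28.3), Uchl1 (498 ± 41.6), Stmn2 (493 ± 12.1) and Syt1 (481 ± 37.7) highest. Of the excitatory list, Camk2a reached 874 ± 129, the vesicular glutamate transporter Slc17a7 713 ± 40.6 and Tbr1 48.8 ± 2.03. Among interneuron genes, Sst (187 ± 37.7) was highest, and the list also held the GABA-synthesising enzyme Gad1 (117 ± 18.4) and Npy (90.8 ± 4.14). The upper-layer list was led by Cux2 (95.4 ± 29.6), Rasgrf2 (65.7 ± 6.51), Cux1 (61.0 ± 10.4) and Lhx2 (30.2 ± 4.37), and the deep-layer list by Crym (64.6 ± 26.6), Bcl11b (31.8 ± 17.5), Etv1 (31.6 ± 2.09) and Tle4 (17.4 ± 3.15). Genes of the immature neuron list were also detected, with Stmn1 at 554 ± 44.4, Gap43 at 254 ± 23.8, Dcx, a microtubule protein of migrating neurons, at 24.8 ± 1.44 and Cd24a at 18.6 ± 3.58. Whether immature cells made these RNAs cannot be told from whole tissue.

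Glial and vascular genes were detected throughout, while most markers of skeletal muscle and blood leukocytes stayed below TPM 1 in both libraries. All 14 astrocyte genes reached TPM 1 in both libraries, with Apoe (864 ± 15.9), Glul (665 ± 10.5) and Aldoc (251 ± 5.97) after Slc1a2. Each oligodendrocyte lineage list had all members at TPM 1 in both libraries. Among them were Olig1 (50.2 ± 7.33) and Pdgfra (29.0 ± 4.40) of the precursor list, and Fyn (78.8 ± 6.75) and Gpr17 (39.6 ± 1.90) of the committed precursor list. The myelinating list held Mbp (403 ± 122), Cnp (85.7 ± 19.4) and Mobp (75.1 ± 23.8). RNA of whole tissue does not show which cells made these transcripts. Microglial Csf1r (33.6 ± 3.42), P2ry12 (32.5 ± 3.17) and C1qb (21.7 ± 2.35), endothelial Slc2a1 (54.7 ± 6.32) and Cldn5 (37.5 ± 0.608), mural Rgs5 (46.6 ± 4.81) and Vtn (46.0 ± 2.35), and Ptgds (747 ± 79.9) and Igf2 (95.7 ± 5.06) of the meningeal fibroblast list were all detected. Border macrophage genes were low, with Mrc1 at 3.96 ± 0.417 and Ms4a7 below TPM 1. Of 6 leukocyte genes only Ptprc, which microglia also express, reached TPM 1 in both libraries (1.21 ± 0.113), and S100a8, S100a9, Cd3e and Ly6g did not reach it in either. Ckm, Myh4 and Tnnt3 of skeletal muscle were below TPM 1, with Acta1 at 4.33 ± 0.120 and Mylpf at 2.05 ± 0.205.

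**Figure D1:**
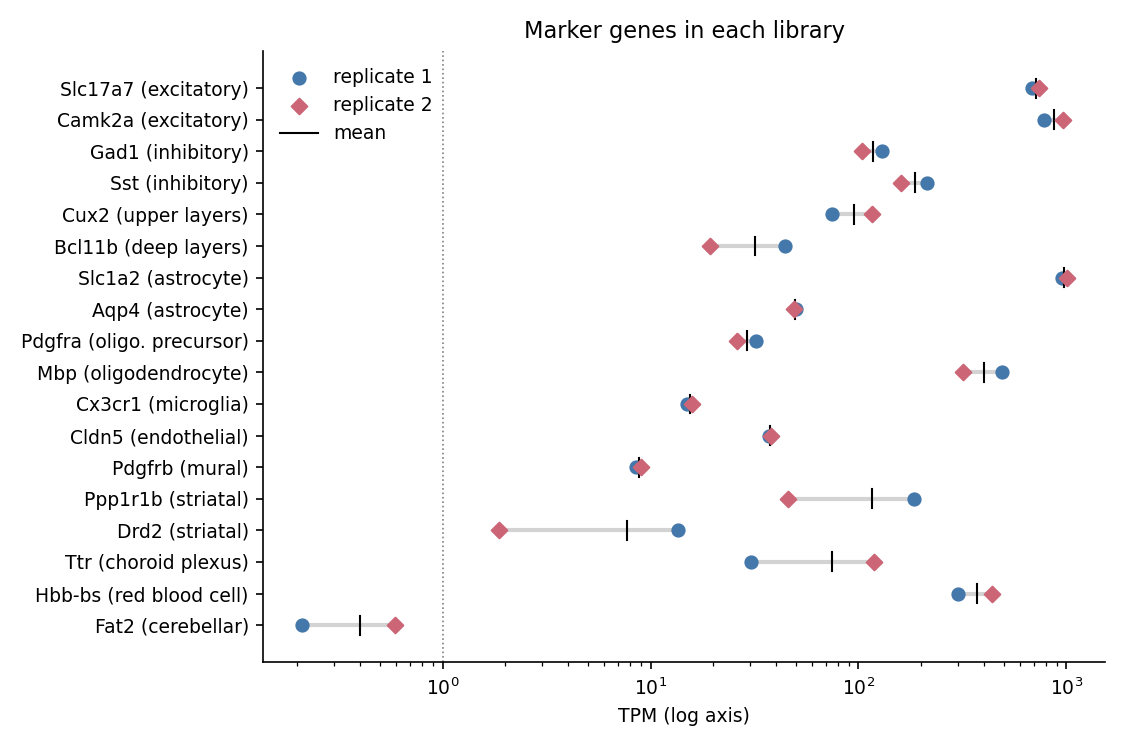
TPM on a log axis of 18 marker genes of the fixed lists in replicate 1 (circles) and replicate 2 (diamonds), with the mean as a black bar and a dotted line at TPM 1. Astrocytic, microglial and vascular markers nearly coincide, whereas Drd2 stood at 13.6 and 1.87 TPM and Ttr at 30.4 and 118 TPM in replicates 1 and 2; the genes shown were picked from the lists after their values were seen.

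Genes typical of neighbouring regions ranged from below TPM 1 to abundant. The striatal list had 10 of 11 genes at TPM 1 in both libraries, and among the highest were Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32 (116 ± 98.7), Penk (64.4 ± 62.3) and Pde10a (52.5 ± 39.2). All 6 cerebellar genes (Fat2, Pcp2, Cbln3, Gabra6, En2 and Barhl1) were below TPM 1 in both libraries. Hippocampal Fibcd1 was at 5.92 ± 0.141, Prox1 at 3.47 ± 0.240, Lct at 2.88 ± 0.601 and Spink8 at 1.56 ± 0.325, with Iyd and Dsp below TPM 1. Thalamic genes included Ramp3 (15.04 ± 4.54), Slc17a6 (14.7 ± 3.72), Prkcd (8.35 ± 1.72) and Tcf7l2 (6.63 ± 0.587), with Gbx2 below TPM 1. Ependymal genes were near the threshold, with Rarres2 at 5.34 ± 0.940, Foxj1 at 1.79 ± 0.198, and Ccdc153, Dynlrb2, Pifo and Tmem212 below TPM 1. Of choroid plexus genes, Ttr was at 74.4 ± 62.3 and Sostdc1 at 2.52 ± 0.0354, while Aqp1 and Otx2 were below TPM 1.

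Receptor, channel and matrix genes had a profile with most members detected. All 15 ionotropic glutamate receptor genes reached TPM 1 in both libraries, with Grin1 (223 ± 1.48), Gria2 (219 ± 0.424), Grin2b (147 ± 20.8) and Grik5 (126 ± 7.52) highest. Of the metabotropic receptors Grm5 (92.8 ± 3.63) and Grm3 (61.3 ± 7.23) were highest, and Grm6, known from the retina, was at 0.01 and 0.02 TPM. Among GABA-A receptor genes Gabrb2 was at 81.0 ± 11.3, and Gabra6 was the member below TPM 1. The vesicle list was led by Syp, Snap25, Vamp2 (557 ± 30.8) and Syt1, and Dlg4 (456 ± 46.7), Shank1 (221 ± 34.2) and Dlg2 (187 ± 12.5) were among the highest of the postsynaptic density list. The sodium channel gene Scn2a (153 ± 5.85) and the potassium channel gene Kcnq3 (71.2 ± 9.62) were among the highest of their lists. In the extracellular matrix list Ncan (153 ± 4.62) and Bcan (143 ± 11.2) exceeded Tnr (70.8 ± 2.90), and Hapln2, Has2 and Has1 were below TPM 1.

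Imprinted, sex-linked and nuclear RNAs were measured in the same libraries. Of 30 imprinted genes 27 reached TPM 1 in both libraries, with the maternally expressed lincRNA Meg3 (chromosome 12, 109541001 to 109571726) at 1621 ± 2.74, Gnas at 859 ± 44.1, Rian at 734 ± 16.0 and Snrpn at 432 ± 3.53. Malat1 was the highest of the long non-coding list (3798 ± 36.3), above Snhg14 (622 ± 33.5) and Snhg11 (273 ± 3.14). Y-linked Eif2s3y (33.2 ± 2.01), Ddx3y (20.1 ± 0.926), Uty (11.1 ± 0.389) and Kdm5d (7.45 ± 1.68) were present, and Usp9y, Sry and Zfy1 were at or near 0. Xist, which coats the inactive X chromosome of females, was at 0.04 and 0.01 TPM and Tsix at 0.04 and 0.02, with Ftx at 10.6 ± 0.757 and Jpx at 5.39 ± 0.721.

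Proliferation genes were low, and stress genes ranged widely. Top2a (2.08 ± 0.304), Rrm2 (2.05 ± 0.233), Cdk1 (1.32 ± 0.212) and Mki67 (1.06 ± 0.0354) were the 4 of 11 proliferation genes at TPM 1 in both libraries, and Ccnb1, Ube2c, Ccnb2, Birc5, Cenpf, Bub1 and Aurkb were below it. Hsp90aa1 was at 426 ± 16.4, whereas Dnajb1 was at 18.2 ± 0.0212, Gadd45b at 6.50 ± 1.15 and Atf3 below TPM 1. Of replication-dependent histones, whose copies share reads, Hist1h4h was highest at 124 ± 5.86, with Hist1h1c at 27.7 ± 3.17.

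Ratios within functional gene pairs compared related genes inside each library. Of 30 pairs, the first gene was higher in 19, the second in 10, and 1 pair was not separated. The chloride exporter Slc12a5, whose rise marks the maturing GABA response, exceeded the importer Slc12a2 (log2 ratio 3.97 ± 0.10, SD, n = 2), and Gria2, which limits calcium entry through AMPA receptors, exceeded Gria1 (1.12 ± 0.22). Grin2b was above Grin2a (-0.65 ± 0.08), Scn2a above Scn1a (-2.03 ± 0.10), Hapln1 above Hapln4 (-1.69 ± 0.36), Vcan above the perineuronal net protein Acan (-2.87 ± 0.45), and Nefl above Nefh (-3.21 ± 0.06). Scn8a exceeded Scn3a (2.25 ± 0.02), Vamp2 Vamp1 (4.61 ± 0.21), Syt1 Syt2 (5.02 ± 0.06), Dlg4 Dlg3 (2.70 ± 0.10), Camk2a Camk2b (1.28 ± 0.24), and Slc17a7 Slc17a6 (5.61 ± 0.45). The glial pairs gave Mbp over Pdgfra (3.76 ± 0.22) and Slc1a2 over Slc1a3 (2.49 ± 0.07), while Aqp4 over Gfap was -0.15 in replicate 1 and 0.16 in replicate 2.

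Pairs of maturity, layer and dosage gave further ratios. Rbfox3 exceeded Dcx (2.52 ± 0.01), Dcx exceeded Mki67 (-4.42 ± 0.13 for Mki67 over Dcx), the neuronal splicing regulator Ptbp2 exceeded Ptbp1 (1.43 ± 0.18), Dnmt3a exceeded Dnmt3b (8.10 ± 0.11), Cux2 exceeded Fezf2 (2.90 ± 0.34) and Sst exceeded Pvalb (3.43 ± 0.72). Each Y-linked gene was below its X-linked partner, at -1.61 ± 0.05 for Ddx3y over Ddx3x, -1.79 ± 0.42 for Kdm5d over Kdm5c, -0.43 ± 0.07 for Eif2s3y over Eif2s3x and -0.79 ± 0.12 for Uty over Kdm6a. The second quantification gave, in the same order, -1.44, -1.53, -0.14 and -0.34. Whether alleles of the 2 parental strains were aligned equally well on mm10 was not examined, so the sizes of these gaps are uncertain. Meg3 exceeded Dlk1 (10.05 ± 1.75) and Snrpn exceeded Ube3a (2.99 ± 0.02). Gad1 exceeded Gad2 by 1.07 ± 0.10 in TPM, but expected counts not divided by length gave -0.13.

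**Figure D2:**
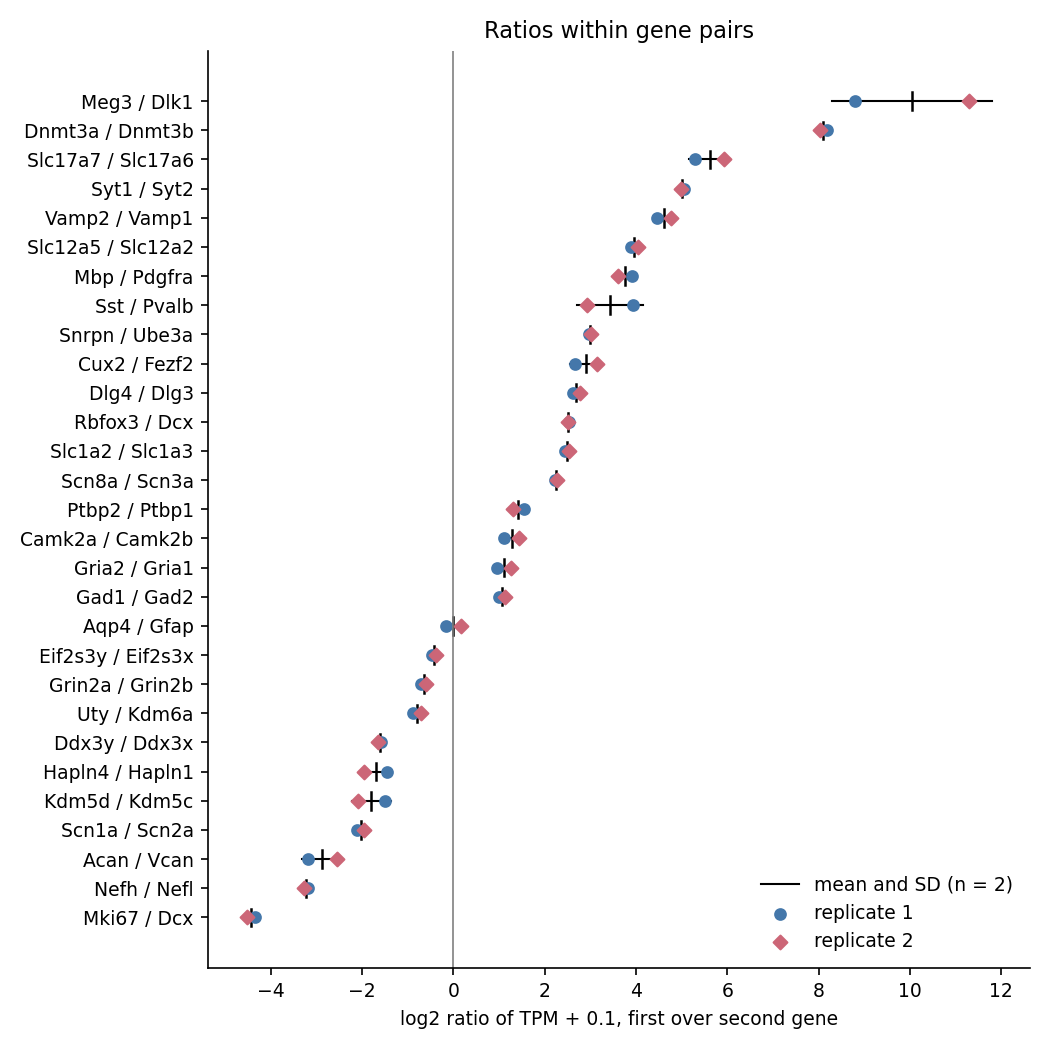
Log2 ratios of TPM + 0.1 within 29 of the 30 gene pairs, first gene over second, in replicate 1 (circles) and replicate 2 (diamonds), with the mean and SD (n = 2) in black. The ratios range from -4.42 for Mki67 over Dcx to 10.05 for Meg3 over Dlk1, and only Aqp4 over Gfap lies on both sides of 0.

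Of 24 genes examined for isoforms, 15 had 1 transcript with over 50% of the gene's TPM in both libraries in the first transcript table, and 10 did in the second. App-201 took 92.8 ± 0.362% of App, the only gene with a share over 75% in both libraries in the first table. Snap25-201 took 73.9 ± 2.37%, Mapt-204 73.7 ± 2.80%, Gria1-201 74.3 ± 1.23%, Gria3-201 73.3 ± 0.124% and Clta-205 72.7 ± 3.51%. Camk2a-203 (64.0 ± 0.645%), Rbfox1-201 (60.2 ± 4.08%), Cdc42-201 (58.4 ± 1.61%) and Gria2-202 (57.8 ± 4.11%) were also over 50%. In the second table Rbfox1-201 was at 49.1% in replicate 1 and 57.1% in replicate 2. Genes with more even shares included Nrxn3 (Nrxn3-205, 38.3 ± 0.674%), Gria4 (Gria4-203, 48.0 ± 1.05%), Grin1 (Grin1-201, 45.6 ± 0.390%) and Dnm1 (Dnm1-201, 43.5 ± 2.27%). By mean share over the libraries, the highest transcript was the same in both tables for 17 of the 24 genes. Among these, the highest transcript of Grin1 and of Dlg4 differed between the libraries in the second table. The tables differed in the highest transcript of Mbp (Mbp-211 and Mbp-201), Gapdh (Gapdh-208 and Gapdh-207), Pkm (Pkm-202 and Pkm-201), Bdnf, Homer1, Dnm1 and Meg3. Shares of Dlg4-203 (54.6 ± 2.30% and 27.8 ± 1.80%) and Gnas-208 (56.8 ± 2.02% and 48.2 ± 0.0779%) lay on both sides of 50%.

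The libraries differed most in striatal genes, which were lower in replicate 2. The 11 genes of the list, all lower, had a median log2 difference (replicate 2 minus replicate 1) of -2.01, or 4.02-fold. Its percentile among matched random lists was 0. Drd2, the dopamine receptor of indirect-pathway neurons (chromosome 9, 49340627 to 49408177), was at 13.6 and 1.87 TPM, Penk at 108 and 20.3, Ppp1r1b at 186 and 46.0, Adora2a at 25.4 and 4.67, Rgs9 at 48.0 and 8.01 and Drd1 at 30.8 and 8.15. Lists of deep layers (median -0.76), myelinating oligodendrocytes (-0.56), thalamic neurons (-0.49), oligodendrocyte precursors (-0.28), inhibitory neurons (-0.28), committed precursors (-0.25) and immature neurons (-0.23) were also lower in replicate 2 in the median. Members higher in replicate 2 numbered 2 of 10 in the deep-layer list, 2 of 7 in the thalamic list, 3 of 10 in the immature neuron list and 2 of 12 in the inhibitory list, namely Vip (13.95 and 23.0 TPM) and Pvalb (13.85 and 21.16). Among gene programs, the replication-dependent histones (-0.19, and -0.15 at percentile 3.35 with a minimum mean of 100 counts), the extracellular matrix list (-0.17), imprinted genes (-0.12) and ionotropic glutamate receptors (-0.10) stood apart in that direction. In these 4 lists 2 of 10, 3 of 10, 9 of 30 and 7 of 15 members were higher in replicate 2, and the ionotropic list's median TPM was 41.7 in replicate 1 and 44.2 in replicate 2.

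Other lists were higher in replicate 2. Excitatory (0.37) and upper-layer genes (0.36) were higher without exception in both lists of 8, with Cux2 at 74.4 and 116 TPM. All 13 immediate early genes, which neuronal activity induces, were higher, with a median of 0.71; Arc was at 21.3 and 51.0 TPM, Egr1 at 58.8 and 101, Egr3 at 28.1 and 43.2 and Nr4a1 at 22.1 and 35.7. Haemoglobin and other red blood cell genes were higher by 0.73, with Hbb-bs at 299 and 440 TPM, Hba-a1 at 269 and 389, Hba-a2 at 209 and 367 and Hbb-bt at 33.1 and 62.9, copies that share reads, and Slc4a1 below TPM 1. The choroid plexus list was higher by 0.97, with 2 of 8 measured members lower, and Ttr was at 30.4 and 118 TPM. Cerebellar genes were higher by 1.39 over 4 measured members, each below TPM 1. Postsynaptic density (0.19), meningeal fibroblast (0.19), mural (0.18) and endothelial genes (0.13) were higher by less in the median. In the mural list 1 of 9 measured members was lower and the median TPM was 8.56 in replicate 1 and 7.38 in replicate 2, and in the endothelial list 4 of 11 were lower.

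In all, 22 of the 41 lists with a percentile stood apart, 12 lower and 10 higher in replicate 2. By chance 2.05 would, if the members of each list varied independently of each other. Members of a cell class or program can vary together, so 2.05 is not a valid yardstick for these lists. Adora2a and Drd1 were named after their values were seen. Among lists that did not stand apart were the astrocyte (-0.02), microglia (0.02), pan-neuronal (0.04), border macrophage (0.20), hippocampal (-0.08), skeletal muscle (0.34), proliferation (-0.01), stress (-0.09), metabotropic receptor (-0.06), GABA-A receptor (0.10), vesicle (0.09), sodium channel (0.04), potassium channel (0.10), Y-linked (0.01), X-inactivation (-0.13), long non-coding (-0.01), small structural (0.01) and mitochondrial (0.08) lists. Ependymal and leukocyte lists had too few measured members for a percentile.

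**Figure D3:**
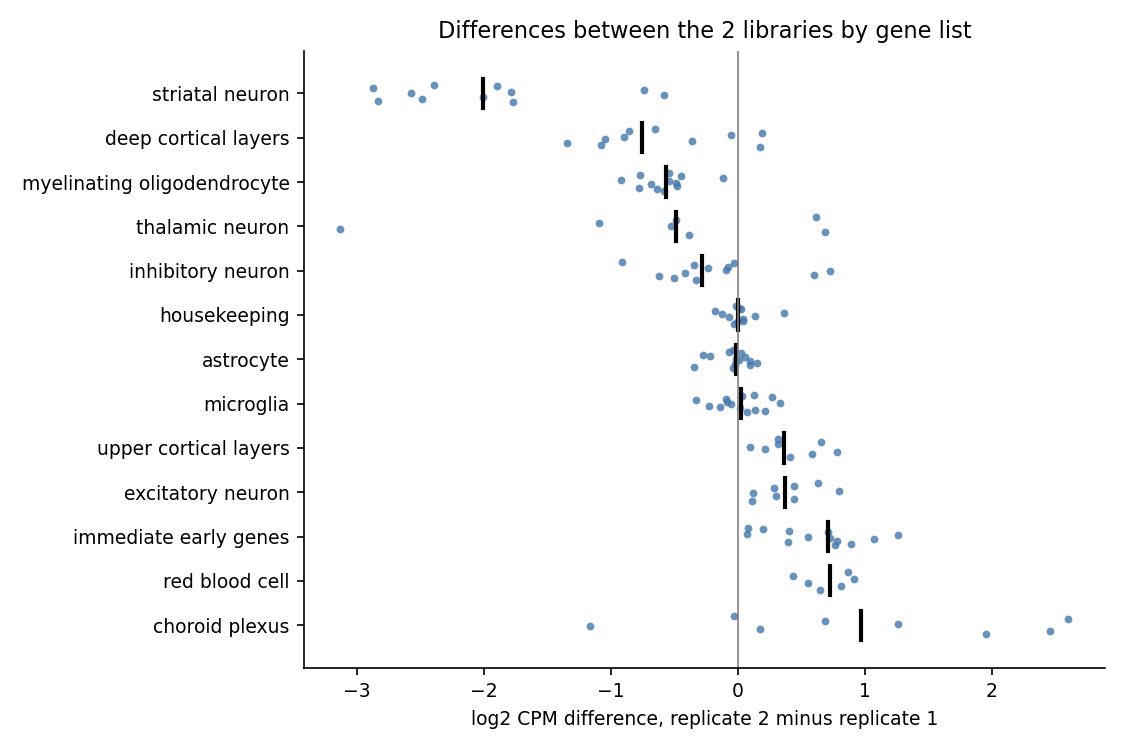
Log2 CPM difference between the libraries (replicate 2 minus replicate 1) of each measured member of 13 of the 43 lists, with the list median as a black bar; the lists shown were chosen after their values were seen. The striatal median lies at -2.01 and the immediate early gene median at 0.71, with astrocyte and housekeeping genes around 0.

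Differences of single genes were mostly small. Of 12624 genes with a mean of at least 100 counts, 97.1% differed by less than 1.5-fold and 103 by 2-fold or more, 87 lower and 16 higher in replicate 2. Of all 18965 genes compared, 748 differed by 2-fold or more, 474 lower and 274 higher. Beside Drd2, Six3 (log2 difference -2.88) and Rgs9 (-2.58), the largest negative differences were those of Ecel1 (-3.05), Ccdc187 (-2.93), the neuropeptide gene Nts (-2.69) and Cd4 (-2.63). The largest positive ones included Ttr (1.96), Fat2 (1.46), A830009L08Rik (1.31), Tnfrsf25 (1.27), Arc (1.26), Gm45062 (1.08) and Egr2 (1.07). The pseudogenes Gm10163 (-7.60), Gm13370 and Gm10240 (2.45 each, with equal counts), the small nuclear RNA copy Gm24497 (-5.32), and Gm20458 (-3.27) and Fam220a (2.25) are uncertain: in the second table the differences were -5.58 for Gm10163, 1.39 for Gm10240, -0.79 for Gm20458 and 0.22 for Fam220a, and Gm24497 had 0 counts.

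The 2 quantifications were compared gene by gene in each library. Spearman correlations across genes were 0.851 over 30050 genes in replicate 1 and 0.855 over 29871 in replicate 2, and 0.980 in both among genes at TPM 1 in both tables. Short genes differed most: of 90 genes whose transcripts were all shorter than 340.1 nt, all 90 had less than 0.1 of their gene-table counts in the second table in each library. Rn7sk (331 nt), at 46819 and 42116 TPM in the gene table, was at 0 and 2.46 in the second.

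**Figure D4:**
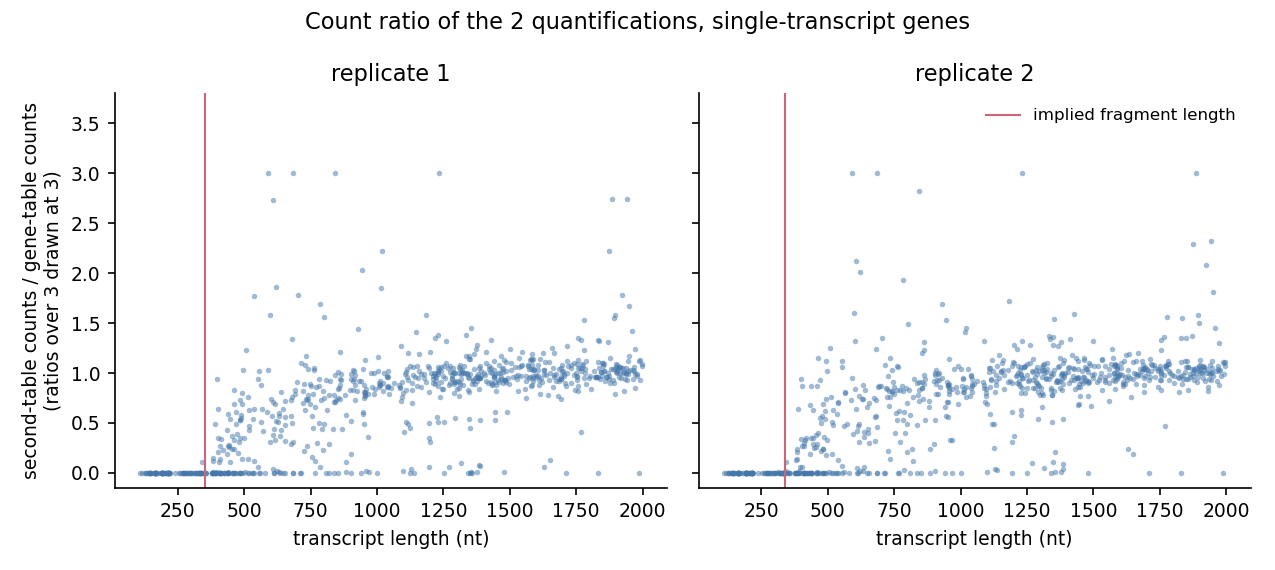
Ratio of second-table to gene-table counts against transcript length in nt for 817 single-transcript genes with at least 50 counts in both libraries and up to 2000 nt, 1 panel per library. Ratios over 3 are drawn at 3, and mt-Nd3, whose values were known, is left out. Points lie at or near 0 left of the line at the implied fragment length (353.2 nt in replicate 1, 340.1 in replicate 2) and many gather near 1 toward 2000 nt, but 44 and 43 of 86 genes from 354 to 499 nt are also under 0.1, and some longer genes lie at 0.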

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

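No paired analysis was possible because both libraries belong to 1 group. Detected genes ranged from 10730 to 17769 over the TPM thresholds, the count threshold and the second quantification, and from 15618 to 15760 with 1 library left out. The coefficient of variation lay between 0.104 and 0.114. The number of genes differing 2-fold, 748, was between 733 and 910 with other size factors, prior count, quantification or unit, but 2297 without a filter on low counts and 103 with a mean count of at least 100, as the numbers of genes entering differ. From 19 to 24 lists stood apart. With a mean count of at least 100 the histone list ceased to (-0.15), and the choroid plexus and cerebellar lists had too few members for a value. No median of a list that stood apart turned its sign under the alternatives that gave one. GABA-A receptor (0.11) and potassium channel (0.12) lists stood apart only in the second quantification. Between 37 and 39 lists had a median of TPM 1, but most medians moved by more than the SD between libraries: 39 up and 2 down in the second table, 42 up after rescaling and 38 down as FPKM. Rescaling and FPKM change the unit by 1 factor per library, so the direction of those moves was fixed in advance. Moves up in the second table include its higher scale, 1.56 and 1.54 times the gene table in the median protein-coding gene. The small structural RNAs moved most, from 5006 to 0.470 TPM in the second table. The first gene was higher in 19 or 20 pairs, but many ratios changed in size by at least the SD between libraries. In the second quantification 16 did. Counts not divided by length moved 21 and turned Gad1 over Gad2 to -0.13. Rbfox3 over Dcx went from 2.52 to 1.04 on such counts, and Syt1 over Syt2 from 5.02 to 5.58 in the second quantification. The SDs printed with the ratios do not cover this dependence. With a share of 0.75, 1 isoform gene passed instead of 15. The correlation between tables, 0.853, was 0.980 among genes at TPM 1 in both and 0.896 on counts. By TPM instead of counts, protein-coding genes took 46.7%, small non-coding RNAs 36.8%, mitochondrial genes 9.09% and spike-ins 0.761%. For genes under 10 counts the depth does not support a difference between the libraries.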

Other observations

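The tests of spike-in scaling and of the second quantification for striatal genes, both tests of the immediate early genes, and the tests of short genes below the implied fragment length and up to 500 nt were chosen after the results were seen. The others were written before the values they measure had been looked at, although the lists' main values were known.

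Striatal genes were lower in replicate 2 by a median of -2.01 on the log2 scale. A further list of 12 striatal markers that had not been looked at, of which none is in another list, had a median of -1.22 (bootstrap 95% interval over members -2.28 to -0.91) with all 12 lower in CPM (Ebf1, at 2.05 and 2.11 TPM, was not lower in TPM), among them Gng7 at 116 and 54.8 TPM, Pde1b at 89.2 and 43.1 and Adcy5 at 81.9 and 39.8, the 3 most abundant. The second quantification gave -2.01, which argues against read assignment; spike-in scaling (-1.97) and removal of trends with GC content and length (-1.95) could hardly have moved the list, as the scaling shifted the median gene by 0.033 and the trends spanned 0.07 and 0.05, too little to produce the difference, and a scaling error would move housekeeping genes (-0.0011) and excitatory genes (0.37) alike. More striatal tissue in the dissection of replicate 1 is a candidate explanation, and the further list moved as it predicts. A difference between animals or pools could not be told apart from it, as the labels do not say how animals were divided between the libraries. Whether more striatal tissue also accounts for the deep-layer difference stays open. The 5 deep-layer genes not typical of striatum had a median of -0.66 with an interval from -1.05 to 0.17.

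Immediate early genes were higher in replicate 2 by a median of 0.71. The second quantification gave 0.67 (interval 0.34 to 0.75), above the 0.2 that read assignment would allow, which argues against it; that the interval had only to exclude 0.2, and not 0.5, was settled after it was seen. A larger cortical share of the tissue could raise them along with excitatory genes, and their excess over the excitatory list was 0.34 with an interval from -0.14 to 0.58, so this explanation stays open. Differences in handling of the animals or tissue before RNA extraction were not tested, as the labels record none.

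Short genes were near 0 in the second transcript table. The effective lengths there imply a fragment length of 353.2 nt in replicate 1 and 340.1 nt in replicate 2, and for 90 genes with shorter transcripts the median count ratio was 0, in line with a length limit of that quantification. The 4 single-transcript genes between the lengths, mt-Nd3 left out, were too few to decide: their median ratio was 0 in replicate 1 and 0.00989 in replicate 2, and 3 of the 4 were under 0.1 in each library. The prediction, under 0.1 in replicate 1 alone, set its bound for replicate 2 too high, since start positions left by a limit would give a median of only 0.014 in replicate 2. mt-Nd3 (348 nt), whose values were known, had 8 and 2066 counts there against 5730 and 6407 in the gene table. For 86 genes from 354 to 499 nt the median ratio was 0.00998 in replicate 1 and 0.0965 in replicate 2. Start positions left by such a limit would give 0.253 and 0.292, so a limit of this form does not account for all of the deficit. The class holds pseudogenes such as Rpl28-ps1 (414 nt, 1033 gene-table and 0 second-table counts in replicate 1) beside genes such as Ndufa1 (419 nt, 678 and 153). Rpl10-ps3, a longer pseudogene of 768 nt, had 2059 and 0. Genes with and without near-identical copies were not separated, so the remaining deficit is not shown to concern length.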
